A study of Mus musculus with 6 samples.

How the data were processed

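The series holds RNA-seq of 6 mouse libraries, 3 wild type and 3 homozygous for the msp3 allele, each from the cranial tissue of an embryo at embryonic day 9.5. Per the labels, RNA was isolated with a column kit and libraries were made with the Illumina TruSeq RNA kit. Per the submitters' processing notes, CASAVA 1.7, bedtools and the mm9 build were used; their roles are not given in the sources used here, nor are the counting rule, the use of strand or the annotation. Labels describe separate embryos.

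The deposited table gives a normalized signal per gene row and library, made by the authors. The values were whole multiples of one step per library, so that whole reads were recovered for 100% of values within a tolerance of 0.001 reads. The steps were proportional to the reciprocals of median-of-ratios size factors computed from the recovered reads. A second deposited sheet, of the Smarcc1 row alone, gives the log2 ratio and signed fold change of the genotype means, computed by the authors per the file headers. The authors' deposited standard deviations use n as the divisor; those printed here use n - 1. The table has 15734 rows, of which 14324 were matched to a gene of the GRCm38 reference by symbol and 1288 by an older symbol, and 122 were not matched. That reference is not the build of the authors, so only its names, chromosomes and distances between genes were used, and no coordinates were converted. A further 12 columns were not used. Zeros were set for whole genotypes: 96 rows were at 0 in all 3 wild-type libraries, 13 in all 3 mutant libraries, and 0 rows were at 0 in only some libraries of a genotype. Such a 0 need not be a true count. These 109 rows have means of at most 4.54 and were outside the main test.

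Because the table was normalized, limma 3.58.1 in R 4.3.3, with a mean-variance trend, was run on log2(value + 1) for the 13329 rows with a mean over the 6 libraries of at least 10, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates changes of low rows. Gene lists (29 fixed, 27 tested, with at least 3 rows) were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation, and with fry. The sex-linked list was described only. Rows near Smarcc1 were compared with Fisher's exact test, 10 Mb to either side. The tests, lists and naming rule were set before the data were examined. The rule names Smarcc1 and 3 other BAF subunits, all rows that pass (up to 10 in each direction), otherwise the rows of smallest p up to 5 given as not passing, and up to 4 members of each list. List members are named here only where row levels fitted the names. The same rule was applied to the rows of chromosome 16 and the first 10 Mb of chromosome 19, an addition made after seeing the data.

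After seeing the data, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were also run on the recovered reads. DESeq2 gave no adjusted p for 2073 rows. Alternatives planned in advance were quantile normalization, equal medians, no filter, a minimum mean of 50, pseudocounts of 0.1 and 5, no trend, array quality weights, a replicate block, leaving out each library, windows of 5 and 20 Mb, a threshold of 0.1, and rows without the X and Y chromosomes.

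The level of broadly expressed genes was examined after seeing the data, with 930 protein-coding genes chosen by family name. Positions of these genes were also moved by up to 2 Mb in steps of 5 kb within windows of 20 Mb that hold at least 8 of them, and the level of the row at the moved midpoint was taken. Several earlier forms of this scan, with other gene sets, windows and distances, were tried first. Tested on simulated data with the real gene layout, the scan found the true shift within 50 kb in 64.0% of 75 simulated windows, and in 86.7% of those with 15 genes or more. When scored against other genes it did so in 41.3%. The simulated shift was constant along a chromosome, and all broadly expressed genes of a window were used. A distance that changes within a window, or a shift chosen on only part of its genes, was not simulated. These rates need not hold there. The limma step was tested on counts simulated for 13329 rows of mutant against wild type: it recovered 48% of rows changed 1.5-fold, 92% at 2-fold and 100% at 4-fold and 8-fold, with 22 false calls beside 170 true ones. That is 11.5% false calls, above the nominal 5%, with 20 further rows shifted as a seeded list counted as neither. The changed rows all had a mean above 100, so the recovery rates need not hold for lower rows. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used. Replicates within each genotype differed by more than counting noise (chi-square per degree of freedom 11.3 to 93.7), so none duplicated another of its genotype. Depth, as reads in rows, ran from 46170743 to 82067578.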

Results

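Polyadenylated RNA was sequenced from the cranial tissue of mouse embryos at embryonic day 9.5, taken from above the pharyngeal arches and the otic vesicles, when the neural tube has just closed in normal embryos. The 6 libraries came from 3 homozygous wild-type embryos and 3 embryos homozygous for msp3, an allele of Smarcc1, which encodes BAF155, a core subunit of the BAF chromatin remodelling complex. The comparison asks how the transcriptome of the mutant cranial tissue differs at this stage. The sample labels give 19 to 21 somites and the series design gives 21 to 23 somites. The reads counted into the rows of the table numbered 46170743, 64024789 and 58847350 in wild type 1, 2 and 3, and 66637742, 63132575 and 82067578 in mutant 1, 2 and 3. Some reads may have been counted in more than 1 row: 216 rows shared all 6 read counts with another row, among rows with a total of at least 30 reads. Whether rows with few reads matched by coincidence was not tested.

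The gene symbols of the table often did not carry the level that the named gene should have. The row named Actb, for cytoplasmic beta-actin, had a mean normalized read count of 82.1 ± 11.5 (SD, n = 6), and the row named Gapdh, a glycolytic enzyme, 7.78 ± 5.21 (SD, n = 6). The row named Eef1a1, a translation elongation factor, had 35.3 ± 14.3 (SD, n = 6). Of 930 genes of broadly expressed families (ribosomal proteins, proteasome, spliceosome, respiratory chain and the like), 265 had a row with a mean of 1000 or more, which is 28.5%. On chromosome 16 it was 24 of 31 genes (77.4%), and at the start of chromosome 19, in its first 10 Mb on GRCm38, 15 of 15. Elsewhere it was 226 of 884 (25.6%), against 22.6% of the other protein-coding genes there. The odds ratio between both stretches and elsewhere was 16.2 (Fisher's exact test, two-sided, p = 4.69e-16). These stretches were picked after the levels were seen, so the test overstates the contrast. Rows such as Eif4g1, a translation initiation factor, at 157745 ± 10537 (SD, n = 6), and Cfl1, the actin-severing protein cofilin, at 97676 ± 10533 (SD, n = 6), lie in them. Values outside these stretches therefore belong to a row that bears a gene's name, and need not be the level of that gene.

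**Figure D1:**
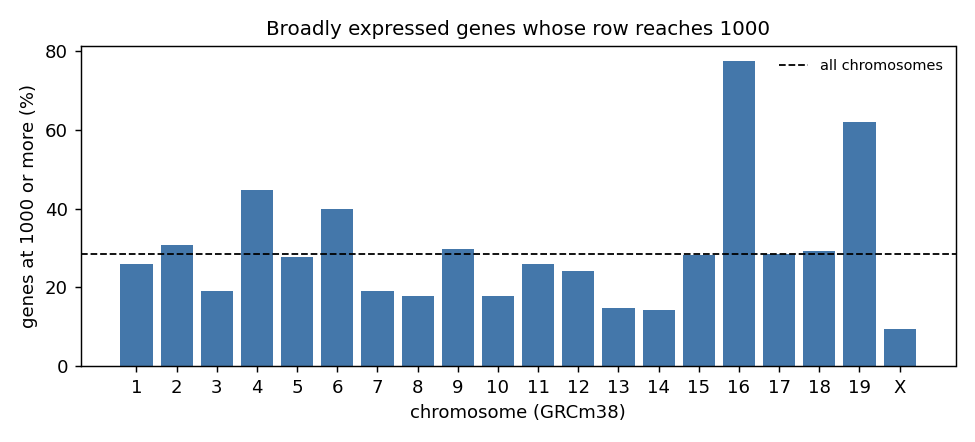
Share of broadly expressed genes whose row reached a mean normalized read count of 1000, by chromosome, with genes that have no row counted as not reaching it; the dashed line is the share over all chromosomes, 28.5%. Chromosome 16 stood at 77.4% and chromosome 19 at 62.1%, and the X chromosome was lowest at 9.52%.

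The row named Smarcc1 was lower in mutants on average, with overlapping values. Its mean normalized read count was 51848 ± 9944 (SD, n = 3) in wild type and 41152 ± 9892 (SD, n = 3) in mutants, a log2 difference of -0.34 with a standard error of 0.18. The limma test gave an adjusted p of 0.495. The log2 difference was -0.20 without wild type 2, -0.53 without mutant 2 and -0.53 with array quality weights. An exact permutation test, two-sided, gave p = 0.3, where 0.1 is the smallest p that 3 against 3 allows. The authors' deposited table gives a signed fold change of -1.26 for this row. Among rows named for other BAF subunits, Smarca4 had a log2 difference of -0.27 (limma, adjusted p = 0.367), Arid2 -0.19 (adjusted p = 0.396) and Smarcb1 -0.34 (adjusted p = 0.432), and none passed. These 4 rows lie on chromosomes 9, 15 and 10, outside the stretches where levels fitted the names.

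In the mutant embryos 3 rows were lower and 0 were higher, of 13329 tested with limma at a Benjamini-Hochberg adjusted p below 0.05. The row named Dhx30 on chromosome 9 fell from 22638 ± 607 (SD, n = 3) to 11953 ± 811 (SD, n = 3), a log2 difference of -0.92 with a standard error of 0.065 and an adjusted p of 0.00418 by limma. The row named Poc1a, also on chromosome 9, fell from 30391 ± 7631 (SD, n = 3) to 7268 ± 914 (SD, n = 3), a log2 difference of -2.04 with a standard error of 0.18 and an adjusted p of 0.0138 by limma. The row named Pla2g7 on chromosome 17 fell from 2080 ± 88.8 (SD, n = 3) to 1189 ± 75.1 (SD, n = 3), a log2 difference of -0.81 with a standard error of 0.085 and an adjusted p of 0.0357 by limma. In each of these rows all 3 mutant values lay below all 3 wild-type values. The rows nearest to passing as higher were Ppat, with a log2 difference of 1.63, and Tspan2, with 1.72, both at an adjusted p of 0.0564. Below them came Dock3 at 0.64 (adjusted p = 0.132), Loh12cr1 at 0.44 and Hfm1 at 0.74 (both 0.2), and on the lower side Col15a1 at -1.39 and Gm6406 at -1.19 (both 0.2). With DESeq2 on recovered reads each of these rows passed, and with edgeR Ppat, Tspan2 and Pla2g7 had an adjusted p of 0.0502, so that Pla2g7 lost its call there. Pla2g7 also lost it without wild type 1 (limma, adjusted p = 0.249).

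**Figure D2:**
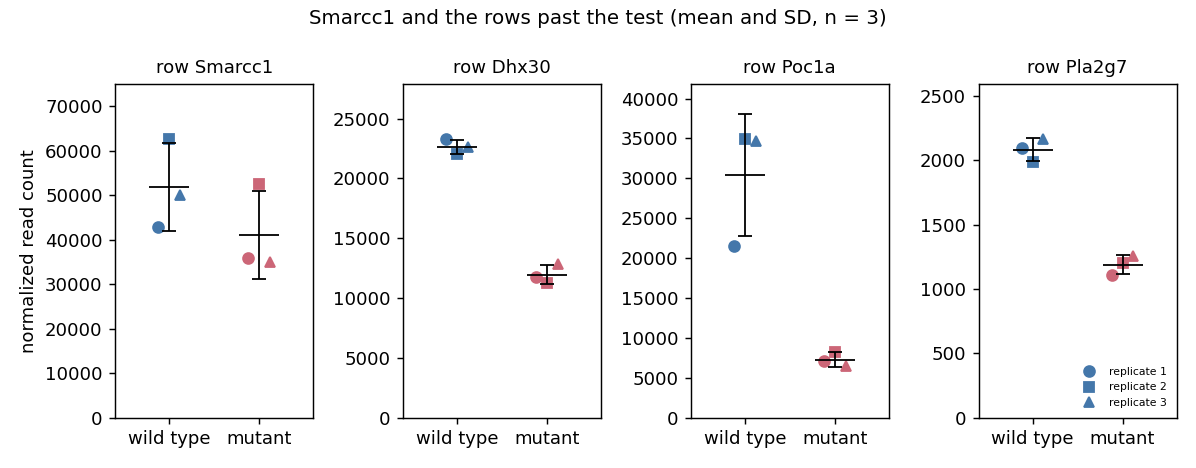
Normalized read count of the rows named Smarcc1, Dhx30, Poc1a and Pla2g7 in each library, with a marker per replicate and the mean and SD (n = 3) of each genotype; each panel starts at 0. Values overlap between genotypes for Smarcc1, and in the other panels the mutant libraries sit below the wild-type libraries, with the Dhx30 row at 22638 against 11953 on average.

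The number of called rows was not stable. With quantile normalization or equal medians it was 5, with Ppat and Tspan2 as the 2 higher rows and the same 3 lower. It was 2 without wild type 1 (Poc1a and Dhx30), 0 without wild type 2 and 0 without wild type 3, 14 without mutant 1, 14 without mutant 2 and 6 without mutant 3, and 0 with limma without a mean-variance trend. On recovered reads, edgeR called 2 rows and DESeq2 called 155 (102 higher and 53 lower), and array quality weights gave 60. At an unadjusted p below 0.05 there were 1444 rows, 708 higher and 736 lower, where 666.5 are expected by chance. In simulated counts for this comparison, 11.5% of the calls made at an adjusted p below 0.05 were false. That share leaves out 20 further shifted rows. The genotypes did not overlap in 2548 rows (19.1%), where chance gives 10%.

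Rows near Smarcc1 on chromosome 9 had low p-values more often than rows elsewhere. The background of these mice is a mix of C57BL/6J and 129/SvImJ, so embryos homozygous for the allele can share sequence around it. Within 10 Mb of Smarcc1, itself left out, 34 of 197 rows (17.3%) had an unadjusted p below 0.05. Elsewhere 1395 rows did (10.7%), an odds ratio of 1.74 with a 95% interval of 1.16 to 2.54 (Fisher's exact test, two-sided, p = 0.00531). Of the 34 rows, 13 were higher and 21 lower in mutants. Over whole chromosomes, chromosome 9 stood at 15.1% against 10.5% elsewhere, an odds ratio of 1.52 (Fisher's exact test, adjusted p = 0.00199), and it alone passed of the 20 chromosomes tested. By the same exact test, the odds ratio near Smarcc1 was 1.29 (p = 0.208) without mutant 2 and 1.37 (p = 0.0795) without mutant 3, and without wild type 1 it was 2.59 (p = 2.23e-05). Neighbouring rows are not independent, so these p-values are too small.

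**Figure D3:**
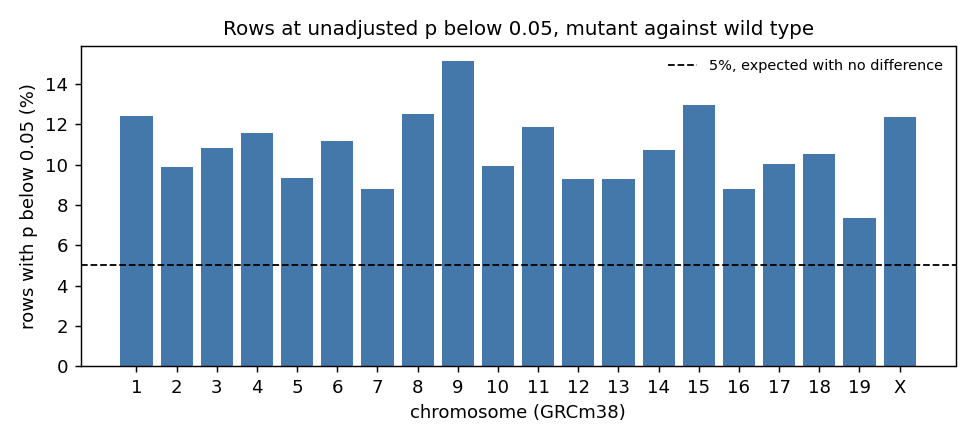
Share of tested rows with an unadjusted p below 0.05 in the comparison of mutant with wild-type embryos, by chromosome; the dashed line marks 5%. Chromosome 9, which carries Smarcc1, is highest at 15.1%, and chromosome 19 is lowest at 7.36%.

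On chromosome 16 and the start of chromosome 19, where row levels fitted the gene names, 0 of 719 rows passed after adjustment within them (limma, smallest adjusted p = 0.384), and 61 had an unadjusted p below 0.05, 37 higher and 24 lower, where 36 are expected. The values given here did not pass adjusted over all rows with limma as planned or with edgeR. With DESeq2 on recovered reads, Cldn5 (adjusted p = 0.00176) and 1300002E11Rik (adjusted p = 0.0112) passed, and with array quality weights Cldn5 did (limma, adjusted p = 0.0445). Over the 17 alternatives the adjusted p ran up to 0.735 for both. Sst, which encodes the neuropeptide somatostatin, had a mean of 171 ± 125 (SD, n = 3) in wild type and 971 ± 294 (SD, n = 3) in mutants, a log2 difference of 2.92 with a standard error of 0.68, which was 1.98 without wild type 1 and 3.50 without wild type 3. Epha3, an ephrin receptor, had 567 ± 239 and 1349 ± 487 (SD, n = 3 each). Gap43, a growth-cone protein of extending axons, had 5546 ± 409 and 6826 ± 310 (SD, n = 3 each), a log2 difference of 0.30. In the other direction, Cldn5, a tight junction protein of endothelium, had 2297 ± 196 in wild type and 1473 ± 255 in mutants (SD, n = 3 each), a log2 difference of -0.65. Tbx1, a transcription factor of the pharyngeal region, had 2570 ± 466 and 1772 ± 285 (SD, n = 3 each), with overlapping values. The Wnt co-receptor Lrp5 had a log2 difference of -0.30, Sipa1 -0.26, Klhl6 -0.43 and Eif4g1 -0.16, and the uncharacterised transcripts 1300002E11Rik and 4930451C15Rik had 0.44 and 0.90.

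**Figure D4:**
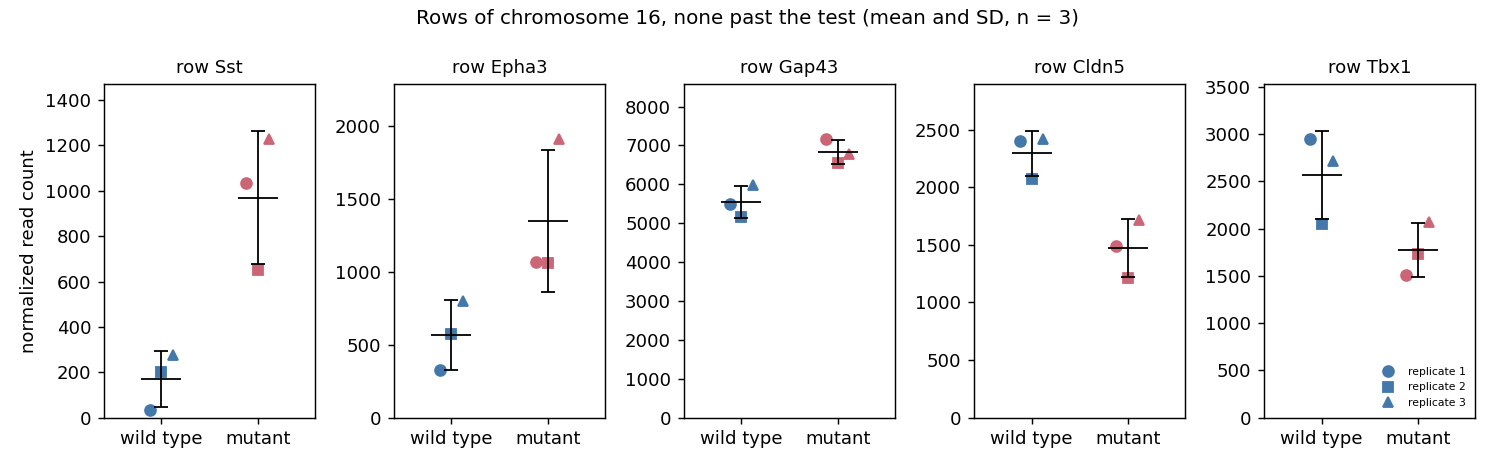
Normalized read count of Sst, Epha3, Gap43, Cldn5 and Tbx1 on chromosome 16 in each library, with a marker per replicate and the mean and SD (n = 3) of each genotype; each panel starts at 0. Mutant means are above wild type for Sst (971 against 171), Epha3 and Gap43 and below it for Cldn5 (1473 against 2297) and Tbx1. None passed the limma test adjusted over all rows, and Cldn5 passed with DESeq2 and with array quality weights.

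No gene list fixed in advance passed: 0 of 27 tested lists had a camera adjusted p below 0.05. These tests rest on row names, most of which lie outside the stretches named above. The smallest adjusted p was 0.181, for BAF complex subunits (3 rows higher and 15 lower of 18), neuronal differentiation (7 higher and 5 lower of 12), pharyngeal arch markers (0 higher and 5 lower of 5) and primitive erythroid markers (2 higher and 6 lower of 8). With an estimated correlation these 4 lists had an adjusted p = 0.932. In every tested list 0 members passed over all genes, and adjusted over the list alone 1 member passed in each of neuronal differentiation, pharyngeal arch, endothelial, surface ectoderm, visceral endoderm, and hypoxia and glycolysis. In the neuronal, pharyngeal arch and endothelial lists it was Gap43 (adjusted p = 0.0416), Tbx1 (0.0448) and Cldn5 (0.01), by limma. The mixed form of fry, which asks whether members change in either direction, gave an adjusted p of 0.00124 for the surface ectoderm list, whose camera adjusted p was 0.876. Neural progenitor markers and the hypoxia list had a camera adjusted p of 0.997, and endothelial markers 0.999. Visceral endoderm markers and immediate early genes had a camera adjusted p of 0.424, and replication-dependent histones 0.735.

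Neural progenitor markers had 6 rows higher and 7 lower, and their member on chromosome 16, the Notch target Hes1, had 4024 ± 259 in wild type and 4273 ± 1288 in mutants (SD, n = 3 each). Neural tube closure genes had 14 higher and 18 lower, with Crebbp, a histone acetyltransferase, at a log2 difference of -0.13 and Cfl1 at 0.06. The cell cycle list had 11 higher and 13 lower, with the replicative helicase subunit Mcm4 at -0.10. Olig2, a ventral neural tube transcription factor, had 961 ± 112 and 1335 ± 548 (SD, n = 3 each), in a list with 3 rows higher and 3 lower. Among other cell types, the neural crest factor Snai2 had a log2 difference of 0.06, the endothelial factor Erg -0.29, and the epithelial factors Ovol1 and Trp63 0.26 and 0.18. The ribosomal protein list had 18 higher and 19 lower, with Rpl24 at 0.27 and Rpl35a at 0.18, and the BAF subunit Dpf2 was at 0.07. None of these passed adjusted over all rows. Without mutant 2, which stood apart from the other libraries, the log2 difference was 0.10 for Rpl24, 0.02 for Rpl35a, 0.001 for Dpf2, 0.03 for Ovol1, -0.07 for Crebbp and 0.15 for Olig2, and without mutant 3 it was 0.41, 0.32, 0.14, 0.57, -0.18 and 0.20. For Olig2 it was 0.38 with all libraries, 0.78 without mutant 1 and -0.0897 with array quality weights. For other genes the sign turned when a library was left out: without mutant 2 the log2 difference was -0.186 for Hes1 (0.0481 with all libraries), -0.0581 for Cfl1 and 0.0535 for Erg, without mutant 1 it was -0.138 for Trp63 and -0.0053 for Snai2, and without wild type 2 it was -0.0102 for Snai2. With array quality weights it was -0.131 for Hes1. No direction was therefore read for these genes or for Olig2. The closure, cell cycle, ventral neural tube, neural crest and ribosomal protein lists and the remaining ones (p53 targets, apoptosis, dorsal neural tube, Wnt and BMP targets, forebrain, midbrain, trunk Hox genes, cranial mesenchyme, macrophages, placodes and muscle) had camera adjusted p-values of 0.876 or 0.887, and the hindbrain list had fewer than 3 tested rows.

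The libraries were similar, and mutant 2 stood apart. Pearson's r between libraries, across rows of log2 values, lay between 0.985 and 0.995; rows are not independent replicates. The first principal component held 36.0% of the variance, with mutant 2 at 44.1 and the other libraries between -20.3 and 3.38. The second held 21.9%, with wild type 1 at 28, mutant 2 at 13.2 and the other libraries between -22.2 and -2.11. Wild type 1 thus also lay away from the other wild-type libraries. The share of variance between genotypes was 28.0%, where 20% is expected with no difference. Of the sex-linked list only Xist and Kdm5d had rows. The row named Xist had 371, 510 and 448 reads in the wild-type libraries and 452, 296 and 545 in the mutant libraries, and the row named Kdm5d, on the Y chromosome, had at most 1 read. Both lie outside the stretches where names fitted levels, so the sex of the embryos was not read from them.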

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

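Tests with edgeR, DESeq2 and the rows with fitting names were chosen after seeing the data. The count of 3 called rows became 5 with quantile normalization, 5 with equal medians (both adding Ppat and Tspan2 as higher), 5 at an adjusted p below 0.1, 60 with array quality weights (38 higher, 22 lower), 155 with DESeq2 on recovered reads, 0 with limma without trend and 0 among rows with supported names. It ranged from 0 to 14 when single libraries were left out. It was 3 with no filter, a minimum mean of 50, either pseudocount and without X and Y rows, and 2 with edgeR; the cause was not tested. Deviations gave no sign that replicate numbers pair the samples (correlations -0.045, 0.000 and 0.059, where any number pair ran from -0.065 to 0.059). This cannot exclude a shared litter or day, which the labels do not give. With the replicate block there were again 3 calls, 2 of them shared: Col15a1 entered and Pla2g7 left. The block changed no other call.

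The number of lists called by camera was 0 in every alternative run; fry's mixed test called the surface ectoderm list. The row named Smarcc1 kept its negative sign in all alternatives, from -0.20 to -0.53 without single libraries, and passed in none. The odds ratio near Smarcc1 stayed above 1, from 1.29 to 2.59 without single libraries, and lost its p below 0.05 without mutant 2 (1.29) and without mutant 3 (1.37). The share of variance between genotypes was 28.0% as planned and 31.3% at a minimum mean of 50, where 20% is expected with no difference in 6 libraries. It was 29.5% to 36.5% without single libraries, where 25% is expected in 5, so these last values are not comparable with 28.0%. Signs reversed, for rows that did not pass, with array quality weights for Olig2 (-0.0897) and Hes1 (-0.131). Without single libraries the log2 difference ran from -0.186 (without mutant 2) to 0.1993 for Hes1, from -0.0581 (without mutant 2) to 0.1524 for Cfl1, from -0.0102 (without wild type 2; -0.0053 without mutant 1) to 0.1225 for Snai2, from -0.138 (without mutant 1) to 0.3851 for Trp63 and from -0.4832 to 0.0535 (without mutant 2) for Erg. Their cause was not tested.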

Other observations

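The tests in this part were chosen after the results were seen, except the move of p-values along the gene order and the comparison with other genes in the scan of positions, whose predictions were written before their results.

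Rows named for broadly expressed genes mostly had low values, and low depth is argued against, since in the same libraries 84.8% of such genes on chromosome 16 and the start of chromosome 19 reached 1000, although these stretches were picked for it. Loss of reads that map to several places, if confined to ribosomal proteins, is argued against as the whole cause. Without ribosomal proteins the share elsewhere was still 27.3%. No other family was set aside, so such loss in other genes was not tested. A candidate explanation, which stays open, is that gene positions of another build than that of the reads were used in counting, displacing rows by a distance that changes along a chromosome. With the shift chosen on the other genes of a window, held-out genes had a mean log2 level of 6.115. This was 1.53 above the average shift (a gain in 32 of 42 windows, sign-flip permutation test, two-sided, p = 2e-05). It was not above the 6.234 with no shift. With no shift a gene that has a row meets that row, but 211 of the 884 genes elsewhere have none. No shift was the best distance in 3 of 44 windows. Scored against other genes at the same shift, the held-out contrast was 1.10 at the chosen shift and 0.38 with no shift. It was higher in 27 of 42 windows and missed the threshold (sign-flip permutation test, two-sided, p = 0.0543). In a pair picked after the levels were seen, the row named Cyth3 on chromosome 5 averaged 343061 ± 35408 (SD, n = 6), against 82.1 for Actb. Actb would fall in the Cyth3 row at a shift of 719.3 to 802.3 kb. Over 25 genes near Actb, the best distance was instead 1920 kb, and 284 of 801 distances scored at least as high as no shift.

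Low p-values were more frequent near Smarcc1. Moving the p-values along the gene order gave as many low values in 1.99% of 13223 moves. This argues against variation shared by neighbouring rows to the degree usual along the genome. It cannot exclude that rows of this stretch vary together for reasons other than genotype. Wild type 1 with mutants 1 and 3, set against the other libraries, gave an odds ratio of 2.13. Wild type 1 with mutants 2 and 3 gave 1.93. A single library stays open: the odds ratio was 1.29 without mutant 2, but leaving out mutant 3 also ended the call. Strain variants linked to the allele may contribute and cannot be told apart from the allele, since they go together in the design; 21 of the 34 rows were lower. The 6 libraries make 10 splits, too few for a share below 0.05: the odds ratio was 1.74 for the real split and 2.13 for the highest other, and 3 splits were as high.

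The row named Dhx30, a neighbour of Smarcc1, was lower in mutants and may hold reads of Smarcc1 if positions are displaced there. This cannot be told apart from a change of Dhx30 itself, because the best distance differed between local scans. In the scan window on chromosome 9 that holds Smarcc1, with 11 genes, it was -100 kb (11.8 against 10.4 with no shift). That lies within -122.6 to -47.7 kb, the range that would lay Smarcc1 over the Dhx30 row. With the 10 genes nearest in the other scan, around Smarcc1, it was -355 kb, outside that range. Over 10 genes near Smarcc1, 32 of 801 distances scored at least as high as no shift, no shift included. Of the 15 distances that would lay Smarcc1 over the whole Dhx30 row, 6 scored above no shift, the highest 11.6 against 9.85, as the explanation needs. Among all the remaining distances of the 801 tried, another 25 also did, the highest 12.3. In this scan of 10 genes, distances above no shift were thus a larger share inside the range, but the highest score lay outside it. Neighbouring distances are not independent.

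The splits of the 6 libraries were also counted for the calls. The real split gave 3 called rows and the highest other 2, with 1 split as high, the real one. It gave 0 called lists and the highest other 2. Since no count can lie below 0, all 10 splits were as high by construction, and this count decides nothing. The number of splits is too small for a share below 0.05.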
